A study of Mus musculus with 2 samples.

How the data were processed

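The samples were 2 biological replicates of H3K36me3 ChIP-seq on mouse stomach at embryonic day 15.5, pooled from 78 and 62 embryos of strain B6NCrl with both sexes mixed. ChIP-seq sequences the DNA bound by a protein or histone mark after immunoprecipitation with an antibody, here against H3K36me3. Per the labels, the libraries were sequenced on Illumina HiSeq instruments. The text deposited beside the files lists 2 technical replicates for replicate 1 and 3 for replicate 2 under each list, and a single list per biological replicate was deposited.

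The authors deposited peak lists in narrowPeak form on the mm10 assembly. A list per replicate was derived from that replicate's filtered alignments, the pooled list from the alignments of both replicates, and the replicated list from the 3 other lists, per the deposited descriptions. The labels name a possible control experiment. The aligner, the peak caller, their versions and the rule behind the replicated list are not given in the sources used here. Each deposited peak has a ratio, the fold enrichment computed by the authors' caller, which ranged from 1.17 to 9.25 in the pooled list and was used only to rank peaks within a list. The deposited lists also give each peak's −log10 p-value and −log10 q-value. The lowest −log10 p was 2.02 in each per-replicate list, and the lowest −log10 q was 0.436 in replicate 1 and 0.399 in replicate 2, so the lists include weak peaks, as a permissive threshold gives. The share of peaks with a −log10 q of at least 5 was 8.14% in replicate 1, 4.31% in replicate 2, 20.3% in the pooled list and 39.2% in the replicated list. No read counts were given, so depth per sample is unknown, and a gene without a peak may lie below what that depth could detect. Signal tracks and alignments were not analysed here.

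Analyses used chromosomes 1 to 19, X and Y. No peak ran past the end of its chromosome in the GRCm38 assembly, which is the sequence of mm10. Gene models were those of GENCODE release M21 on GRCm38, with 21938 protein-coding genes on these chromosomes. Coordinates are 1-based mm10 positions. Intervals were merged and intersected with Python 3.11.15 and numpy 2.4.6, and the overlap of the replicates was checked against bedtools 2.31.1, which gave the same number of shared bases. Intervals for shares are 95% exact binomial intervals from scipy 1.17.1.

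A gene body was the whole annotated span. Coverage was the percent of a gene body in peaks, computed for each replicate and given as mean and SD. A protein-coding gene of at least 2 kb was called marked at 20% coverage in both replicates. Members of gene lists entered at any length and were called marked by the same 20%. Exons came from the longest basic protein-coding transcript of a gene. Flanks were 5 kb, and a base in several classes counted first as gene body, then as upstream, then as downstream. Domains joined replicated peaks at most 1 kb apart. Chance levels came from 100 circular shifts between the first and last peak of a chromosome, and from 20 shifts for the share of peaks that touch the other replicate. The 10 classes by fold enrichment were uneven in size because of tied values.

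Before the data were examined, 31 gene lists were fixed, for gastric epithelium, mesenchyme, muscle, matrix, nerve, vessel and blood cells, for other organs, and for housekeeping and other gene families. A list's mean coverage was placed among 10000 random lists of the same size, drawn from protein-coding genes outside the list matched in 10 classes of length, and a gene could recur within a random list. Ties in the percentile were split evenly between below and above. Percentiles above 99 or below 1 were called apart. Of the 31 lists 5 were above, 18 below and 8 within these limits. The symbols Cblif and Raldh2 were not found in the annotation. The genes named in the text followed a rule fixed at the same time: the 10 highest genes of at least 10 kb that overlap no other protein-coding gene, up to 2 highest and 2 lowest members of each list with ties in alphabetical order, the 5 genes of at least 10 kb with the largest difference between replicates, and the genes in the 5 longest domains. Setd2, Ctnnb1, Flna, Kdm5c, Tagln, Mfap4 and the genes beside or overlapping other named genes were named after their values were seen.

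The calling of marked genes was tested on simulated peaks, and the calling of lists on random lists. Genes filled to 60% or 25% of the body pass the limit by construction and tell nothing of sensitivity. Of 15700 genes that were not filled, 0.102% were called marked. Background peaks were shifted independently in the 2 simulated replicates, so this rate does not cover background that real replicates share. Of 1000 random lists of 20 genes, 2.20% were called apart. Such lists are random like those they are placed among, so the percentile limits fix a rate near this by construction. The rate therefore tells nothing of how well a real difference is found. With 1 group of 2 replicates no test between groups was possible, and differences are set against the spread of the replicates. Alternatives covered stricter q-values, other overlaps, gaps, flanks and thresholds, the pooled or replicated list, each replicate alone, random lists not matched on length, and genes that overlap no other gene. The ratio of X to autosomes in each replicate alone was added after seeing the data. Peaks on other contigs were left out of all comparisons.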

Results

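H3K36me3, trimethylation of lysine 36 of histone H3, is a mark that textbook knowledge places along transcribed gene bodies. Its genome-wide distribution was measured by ChIP-seq in mouse embryonic stomach at day 15.5, in strain B6NCrl with both sexes pooled. The labels give a single group with 2 biological replicates. Replicate 1 held stomachs of 78 embryos and 2 technical replicates, and replicate 2 held stomachs of 62 embryos and 3 technical replicates. The data were 4 lists of peaks on the mm10 genome. A separate list was given for each replicate, the pooled list was called on both together, and the replicated list was derived from the other 3. Sequencing depth is unknown, since the lists hold no read counts. On chromosomes 1 to 19, X and Y, replicate 1 had 138103 peaks covering 54.5 Mb and replicate 2 had 131052 peaks covering 46.4 Mb. The design holds no second tissue, age or treatment, so the comparisons below concern where in the genome the mark lay and how far the replicates matched. Each value written with ± is a mean and SD of the 2 replicates (n = 2) unless stated otherwise.

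H3K36me3 lay almost wholly inside protein-coding genes, and mostly in their later parts. Gene bodies held 95.4% of the bases of the replicated list, 94.9% in replicate 1 and 94.4% in replicate 2. Circular shifts of the same peaks along their chromosomes placed 42.3% there on average and at most 45.5% in 100 shifts, so the observed share was 2.26 times that of the shifted peaks. The 5 kb upstream of gene starts held 0.580% of replicated peak bases against 3.34% for shifted peaks. The 5 kb downstream of gene ends held 3.39% against 2.60%, and all other sequence held 0.605% against 51.8%. The downstream share also exceeded the upstream share in each replicate, at 3.54% against 0.621% in replicate 1 and 3.56% against 0.684% in replicate 2.

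Along the 2117 marked genes of at least 10 kb, coverage rose from 1.01% ± 0.188 of bases in the first of 20 equal bins to 50.8% ± 3.09 in bin 18, and stood at 40.3% ± 2.80 in the last bin. The mean of the last 5 bins was 3.28 times that of the first 5 in replicate 1 and 3.66 times in replicate 2, giving a mean ratio of 3.47 ± 0.271. Restricting the peaks to a −log10 q of at least 5 left 94 such genes and a ratio of 5.17.

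**Figure D1:**
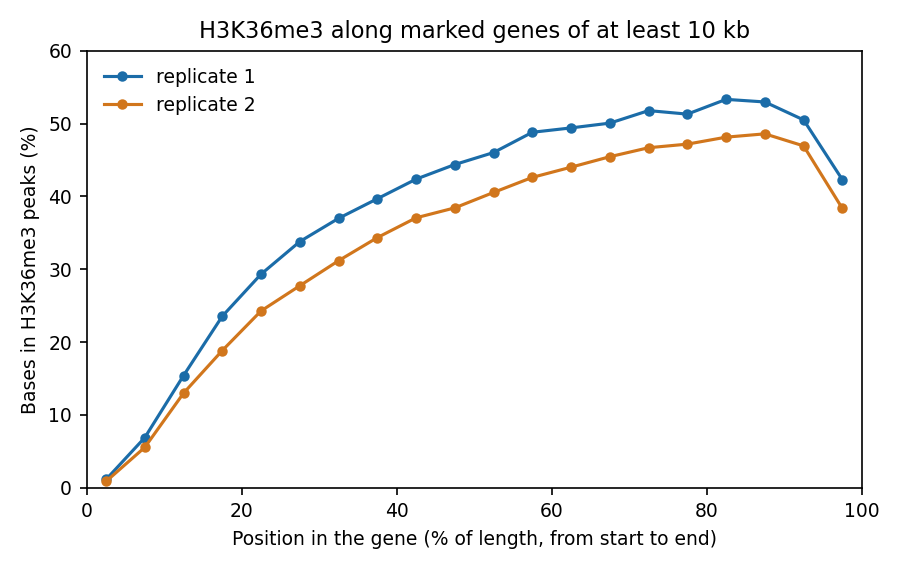
Mean percent of bases in H3K36me3 peaks (y axis) in 20 equal bins from gene start to gene end (x axis, percent of gene length) over 2117 marked protein-coding genes of at least 10 kb. Each line is a replicate, and both climb from about 1.15% and 0.882% in the first bin to their highest values late in the gene.

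Exons were more often in peaks than introns. In 2830 marked genes with at least 3 exons, and with the first exon and first intron left out, 53.0% ± 2.34 of exon bases and 39.2% ± 4.30 of intron bases were in peaks. The ratio was 1.29 in replicate 1 and 1.42 in replicate 2, with a mean of 1.36 ± 0.0896. Between windows of 100 bp of the same gene the ratio was 1.28 ± 0.0717. Between windows of the same gene and the same GC class it was 1.16 ± 0.0246. With position, GC class and freedom from repeats matched together it was 1.04 ± 0.00177, in windows where the ratio within genes was already 1.06 before that matching.

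A gene was called marked when at least 20% of its annotated span lay in peaks of each replicate. Of 20350 protein-coding genes of at least 2 kb, 2916 were marked, or 14.3%, and 8551 held no peak in either replicate. Of the marked genes, 903 overlapped another protein-coding gene, and a peak in shared sequence counted for both genes. Replicate 1 alone reached the threshold for another 879 genes and replicate 2 alone for 300. If the replicates had marked genes independently, 599.7 genes would have been shared. The count depends on the threshold, with 5136 genes at 10% of the gene body, 697 at 40%, and 157 when peaks needed a −log10 q of at least 5. Marked genes were commonest at middle lengths. The share marked was 8.86% of genes of 2 to 5 kb, 22.5% of genes of 10 to 20 kb and 1.28% of genes of 100 kb or more.

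The most fully covered genes had varied functions and included a pair of zinc finger genes. Among genes of at least 10 kb that overlap no other protein-coding gene, the highest coverage was found at Zfp110 (chromosome 7, 12834761 to 12850577, plus strand), with 76.7% ± 5.92 of its span in peaks. Zfp606, on the same chromosome (12478293 to 12496235, plus strand), had 74.9% ± 6.38. Fasn, the fatty acid synthase gene (chromosome 11, 120805846 to 120824547, minus strand), had 74.4% ± 4.98. Kmt2b, a histone H3 lysine 4 methyltransferase gene, had 74.3% ± 0.872, and Eif3d, a subunit of a translation initiation factor, had 72.7% ± 1.11. The other 5 were Hjurp, the chaperone of the centromeric histone CENP-A (71.5% ± 1.85), Prrc2a (70.9% ± 9.54), the mitochondrial RNA polymerase gene Polrmt (70.5% ± 3.45), the cell polarity gene Scrib (70.4% ± 2.51) and the splicing factor gene Prpf8 (69.7% ± 6.78). The order among these 10 genes differed in part between the replicates, with Zfp110 highest in replicate 1 (80.9%) and Fasn in replicate 2 (77.9%), while Zfp110 exceeded Prpf8 in both.

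Joining replicated peaks at most 1 kb apart gave 36436 domains with a median length of 804 bp. All 936 domains of 10 kb or longer touched a protein-coding gene. The longest ran for 85.5 kb on chromosome 4 (139405951 to 139491485) and took in 61.1% of Ubr4, an E3 ubiquitin ligase gene. It passed the annotated end of Ubr4, at 139489588. Next came 48.2 kb over Trrap, a scaffold of histone acetyltransferase complexes (chromosome 5), and 43.7 kb over the spectrin gene Sptan1, which reached 1170 bp into the converging gene Wdr34 (chromosome 2). A domain of 38.1 kb covered the end of the transcription factor gene Gtf2i (chromosome 5), and a domain of 37.8 kb covered the end of the non-muscle myosin gene Myh9 (chromosome 15). Each of these 5 domains had between 71.7% and 77.0% of its bases in peaks, averaged over the replicates. With a gap of 3 kb the number of domains was 19842, and in replicate 2 alone it was 56971. The longest domain depended on these settings too, at 44.1 kb with a gap of 0.5 kb and 49.8 kb in replicate 2 alone.

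Cell cycle, housekeeping and ribosomal protein genes as lists held more of the mark than random lists, though many members were not marked. Lists of genes were fixed beforehand and compared with random lists of protein-coding genes matched on length, as a description of these libraries. Of 24 cell cycle and DNA replication genes 18 were marked, with a mean coverage of 34.4% ± 6.79 against 9.72% for random lists. The replicative helicase genes Mcm2 (57.2% ± 1.92) and Mcm5 (52.1% ± 8.06) were highest, and the DNA polymerase alpha gene Pola1, on X, was lowest at 0.0835% ± 0.0417. Ccnb1, a mitotic cyclin gene, had 16.2% in replicate 1 and 0% in replicate 2. In the housekeeping list 10 of 24 genes were marked, led by the translation elongation factor gene Eef2 (70.5% ± 4.62) and the chaperone gene Hsp90ab1 (65.0% ± 8.21). Eef1a1, another elongation factor gene, had 0.869% ± 1.23, and Hprt, on X, had 2.93% ± 0.932. Of 83 ribosomal protein genes 38 were marked, with Rps28 (60.1% ± 8.76) and Rps3 (56.3% ± 4.25) at the top and Rpl10 and Rpl10l without any peak. Of these 38 genes, 10 overlapped another protein-coding gene, among them Rps28, which overlaps Kank3. All 3 lists lay above all 10000 random lists.

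The enzymes and readers of H3K36 methylation and the zinc finger genes also stood above all 10000 random lists. In the H3K36 list 13 of 24 genes were marked, 6 of them overlapping another protein-coding gene. Its highest members were the demethylase gene Kdm4a (66.1% ± 7.23) and Brpf1, which encodes a reader of the mark (54.5% ± 0.934). Setd2, the main H3K36 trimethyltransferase gene, had 28.9% ± 8.48 and was singled out after its value was seen. Its lowest members were the DNA methyltransferase gene Dnmt3b (2.78% ± 1.72) and the demethylase gene Kdm4c (3.46% ± 1.63). Among 391 genes with names that start in Zfp, 112 were marked and 61 held no peak. Zfp869 (80.3% ± 7.05) and Zfp110 led this list, and Zfp174 and Zfp185 were among those with no peak. Its mean coverage was 16.5% ± 2.14, which is 1.65 times the mean of random lists.

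Structural genes of the stomach wall were partly marked. Of 22 fibroblast and extracellular matrix genes 6 were marked, among them the collagen gene Col1a1 (chromosome 11, 94936224 to 94953042, plus strand), with 38.6% ± 5.12, and the fibronectin gene Fn1, with 30.4% ± 7.16. Mfap4 (26.5% ± 3.00), also marked, overlaps Mapk7. Postn (0.907% ± 1.28) and Dcn (1.75% ± 1.46) were lowest. The list's mean of 14.1% ± 1.98 lay at percentile 97.9 of random lists, short of the limit of 99 set for calling a list apart, and at 26.7 with a −log10 q of at least 5. Of 20 smooth muscle genes 6 were marked, led by the smoothelin gene Smtn (41.4% ± 0.741) and the transcription factor gene Srf (40.6% ± 3.73). Another of them, Tagln (22.3% ± 2.87), overlaps Pcsk7. It starts 1798 bp past the end of Sidt2 on the same strand, which had 34.5% ± 1.18. Lmod1 held no peak and Ldb3 had 0.180% ± 0.254. This list stood at percentile 91.3, within the range of random lists.

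Genes of epithelial junctions and of signalling lay within the range of random lists. Among 20 genes of epithelial junctions and keratins, Jup, the plakoglobin gene (33.5% ± 3.23), and Esrp2, an epithelial splicing regulator gene (30.8% ± 10.8), were marked. Esrp2 overlaps Nfatc3. Cldn3 and Cldn18 had no peak, and the list stood at percentile 29.1. Of 27 signalling genes 3 were marked: the Hedgehog receptor gene Ptch1 (30.9% ± 8.36), Notch1 (29.3% ± 0.336) and the β-catenin gene Ctnnb1 (27.1% ± 4.49). Bmp4 and Fgf10 held no peak, and the list stood at percentile 31.0. Of 19 annotated genes for products of mature gastric glands, Ghrl, the ghrelin gene (chromosome 6, 113716119 to 113719880, minus strand), was the one marked, at 27.0% ± 5.53. The gene next upstream on the same strand, Sec13, lay 8181 bp away and had 46.7% ± 1.56; it was looked up after the value of Ghrl was seen. Muc6 followed at 3.56% ± 0.990, while the proton pump genes Atp4a and Atp4b held no peak. This list fell at percentile 0.50, below the lower limit of 1, but at 1.32 in the replicated list and at 1.72 without overlapping genes, where the call ended.

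Most of the further lists, of cell type regulators and of markers of other cell types and organs, had little coverage by peaks. The share of each cell type in the tissue was not measured. The 11 such lists called below random lists are grouped here, chosen by that call. Those for blood, lung and interstitial cells of Cajal were not called apart. The list of mature gastric gland products, described above, was also called below but is left out here, and its member Ghrl was marked. In the 11 lists, with 205 genes in all, no gene was marked and 152 genes held no peak in either replicate. The highest coverage was 9.25% ± 4.50, at Meis1. Over all protein-coding genes of at least 2 kb, 14.3% were marked and 42.0% held no peak in either replicate. At unknown depth, low coverage does not show that the mark was absent. With a −log10 q of at least 5 the call ended for squamous forestomach (percentile 2.85), intestinal epithelium (3.42), pancreas (1.48) and skeletal and cardiac muscle (1.30). The lists covered transcription factors of gastric epithelium, where Hnf1a (3.17% ± 0.684) and Klf5 (3.10% ± 2.57) were highest and Elf3 and Foxa1 held no peak (percentile 0.040). In the list of gastric mesenchyme transcription factors Meis1 and Meis2 (4.73% ± 1.89) were highest, and Barx1 and Foxf1, which act in stomach mesenchyme, held no peak (percentile 0.39). With a −log10 q of at least 5 this list stood at 4.44, and without overlapping genes at 2.01, so the call ended under both. Squamous forestomach genes (percentile 0.050) reached 2.26% ± 1.14 at Perp and 0.0458% ± 0.0648 at Trp63. Enteric neural crest genes reached 8.78% ± 5.67 at the receptor gene Erbb3 and 0.902% ± 1.28 at Ednrb, and endothelial genes 3.38% ± 1.34 at Eng and 2.09% ± 0.955 at Egfl7. Neither list was as high as any random list.

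Genes of most other organs behaved likewise. Coverage was at most 2.76% ± 0.870 among intestinal epithelium genes (Vil1, percentile 0.010), 1.18% ± 1.67 among liver genes (Hpx), 0.370% ± 0.524 among pancreas genes (Pnlip), 0.482% ± 0.0911 among skeletal and cardiac muscle genes (Ttn), 1.03% ± 1.46 among brain genes (Slc17a7) and 0.567% ± 0.128 among germ cell genes (Tdrd1). The last 5 of these lists stood at percentile 0. The lung list stood at percentile 2.16, and at 40.8 with a −log10 q of at least 5, with Ager at 13.1% ± 2.67, and the list for interstitial cells of Cajal at 2.70, with the gap junction gene Gja1 at 4.84% ± 0.590 and Kit at 3.57% ± 0.890, so neither was called apart. In the list of blood and immune cells 15 of 20 genes held no peak. Its single marked member was the macrophage gene Cd68 (75.4% ± 6.81), which starts 782 bp past the end of Eif4a1 on the same strand, a translation factor gene with 53.9% in replicate 1 and 32.7% in replicate 2. Csf1r followed at 4.57% ± 0.670, and the list stood at percentile 17.4.

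Among the remaining lists, 31 of 34 Hox genes held no peak, and the highest, Hoxb3, had 0.758% ± 0.00862. Anterior Hox genes stood at percentile 0.010 and posterior ones at 0.095. Both calls ended with a −log10 q of at least 5 (1.39 and 10.04) and without overlapping genes (4.06 and 1.04). The posterior list had a coverage of 0% throughout, so its percentile rose only because more random lists also fell to 0%. No member of the 1093 olfactory receptor genes, 327 vomeronasal receptor genes, 65 replication-dependent histone genes or 57 keratin-associated protein genes was marked. Of the histone genes, Hist1h2aa was the one with a peak, with 47.7% of its span in replicate 2 and 0% in replicate 1. The histone list stood at percentile 0.21, but the call ended in replicate 2 alone (2.15), with a −log10 q of at least 5 (6.01) and without overlapping genes (3.97). Olfactory and vomeronasal receptor genes stood at percentile 0 and keratin-associated protein genes at 0.0050, a call that ended with a −log10 q of at least 5 (12.1) and without overlapping genes (1.01), again with a coverage of 0% throughout and ties with random lists. Of 25 imprinted genes, Nnat (48.9% ± 2.57), which lies within Blcap, and Igf2r (23.5% ± 2.01) were marked, while Ascl2 and H19 held no peak. The imprinted list stood at percentile 77.5.

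**Figure D2:**
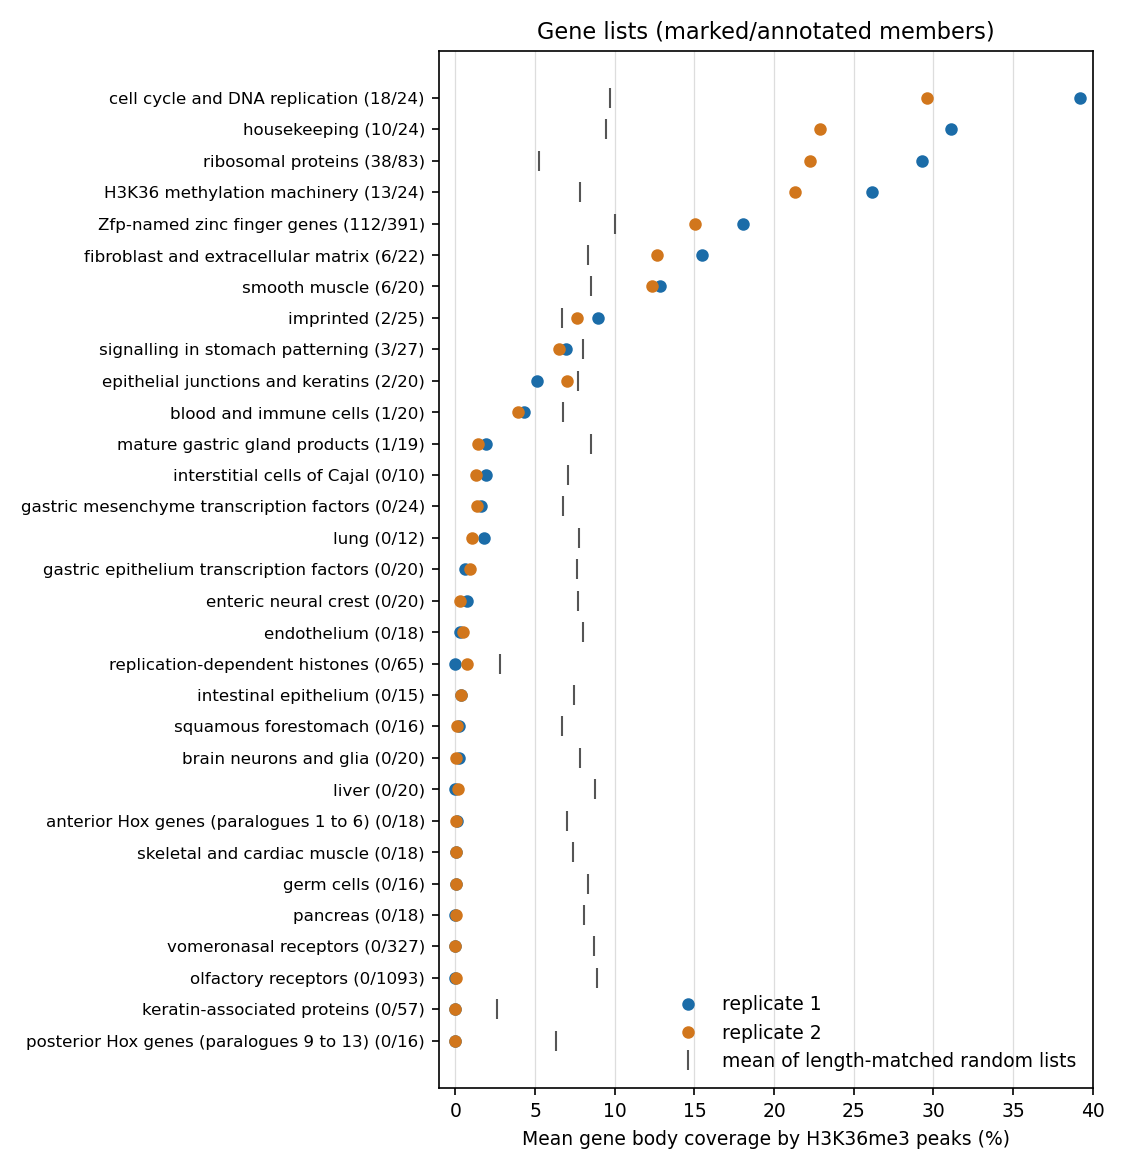
Mean percent of the gene body in H3K36me3 peaks (x axis) for the 31 gene lists (y axis, with marked over annotated members), each replicate a point and the mean of length-matched random lists a grey tick. In the 5 lists called above random lists both replicates lie to the right of the tick, and cell cycle genes are highest.

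The sex chromosomes carried few peaks. On X, 0.115% ± 0.0316 of the sequence was in peaks, against 2.04% ± 0.231 of the autosomes. The ratio was 0.0623 in replicate 1 and 0.0494 in replicate 2, with a mean of 0.0559 ± 0.00915, and it was 0.0666 in the pooled list and 0.0154 for peaks with a −log10 q of at least 5. Of 791 X genes of at least 2 kb, 2 were marked, against 2914 of 19408 autosomal genes. They were the actin-binding filamin gene Flna (29.5% ± 3.81) and the histone demethylase gene Kdm5c (24.7% ± 5.48), both named after their values were seen. On Y, 0.00296% ± 0.000119 was in peaks. Among autosomes the mean share ran from 1.28% ± 0.224 on chromosome 3 to 3.49% ± 0.346 on chromosome 11. Protein-coding gene bodies made up 26.3% of X, 33.3% of chromosome 3 and 47.0% of chromosome 11.

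**Figure D3:**
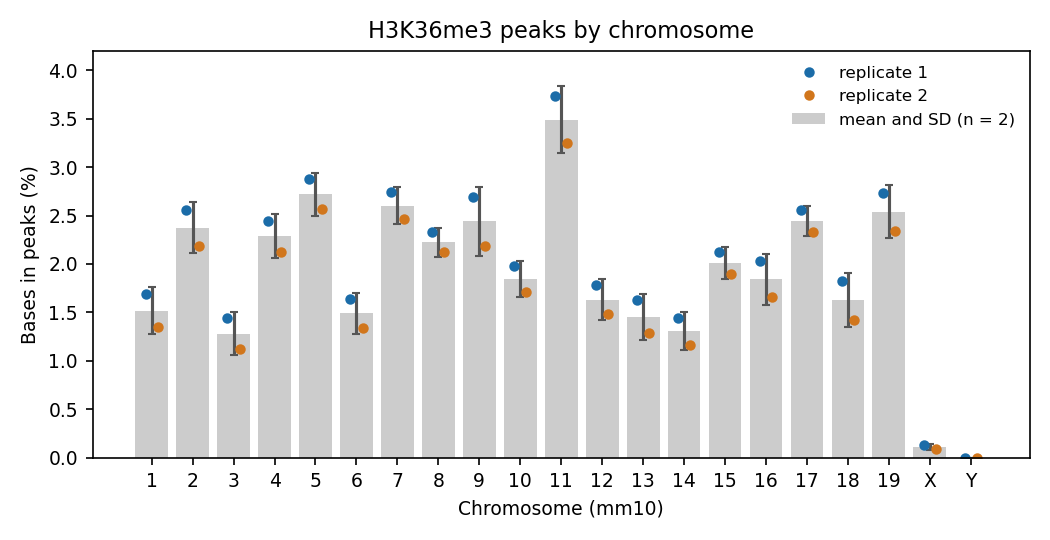
Percent of each mm10 chromosome in H3K36me3 peaks (y axis) for chromosomes 1 to 19, X and Y (x axis). Bars are means with SD of the 2 replicates and points are the replicates; chromosome 11 is highest at 3.49% and X stands at 0.115%.

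The replicates shared far more than shifted peaks did, and peaks of low fold enrichment were shared least often. The replicates had 24.9 Mb in common, which is 32.8% of their union, 45.7% of the peak bases of replicate 1 and 53.7% of those of replicate 2. Circular shifts of replicate 2 gave 1.13% of the union on average and at most 1.33%. A base or more of overlap with the other replicate was found for 56.8% of the peaks of replicate 1 (95% exact binomial interval 56.5 to 57.0) and for 62.3% of those of replicate 2 (62.0 to 62.6), against 3.85% and 4.19% under shifts. These intervals cover counting error only. Among 10 classes by the authors' fold enrichment, the shares were 84.7% and 89.6% in the highest class and 40.9% and 47.5% in the lowest. Peak width, which affects how often peaks touch, was not matched between classes, and the shifts took all peaks together. The mean share was 59.5% ± 3.91, and with peaks held to a −log10 q of at least 5 in both lists it was 30.6%. That limit left 8.14% of the peaks of replicate 1 and 4.31% of those of replicate 2, so fewer peaks remained to be touched.

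**Figure D4:**
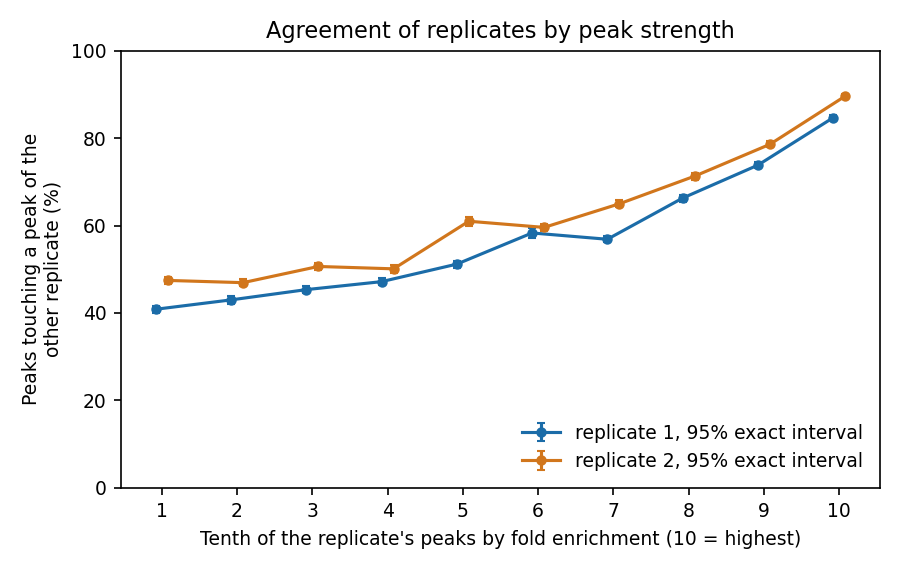
Percent of a replicate's peaks that touch a peak of the other replicate (y axis) in 10 classes of its own peaks ranked by fold enrichment (x axis, 10 is highest), with 95% exact binomial intervals. Both lines end far above their start, at 84.7% and 89.6% in the highest class.

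The replicated list held 83173 peaks over 53.2 Mb, with a median width of 489 bp. Each of its peaks was also a peak of the pooled list, of which it kept 49.5% of the peaks and 70.9% of the bases. Peaks with at least 50% of their bases in peaks of both replicates made up 59.0% of the replicated list and 29.2% of the pooled list. A single shared base in each replicate was enough for 81.0% of the replicated list, and the remaining peaks lacked a counterpart in at least 1 replicate. The pooled peaks that were not kept had a median width of 229 bp.

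Most marked genes of at least 10 kb had more of the mark in replicate 1. Among genes of at least 10 kb, the 5 largest differences in coverage were at Hnrnpu (45.5% against 17.2%), which encodes an RNA-binding protein, Chtop (47.5% against 19.2%), Wdr77 (66.6% against 40.8%), Cebpz (44.0% against 19.2%) and the translation factor gene Eif4g2 (75.1% against 50.5%). Hnrnpu overlaps the protein-coding gene Cox20, Wdr77 overlaps Atp5f1 and Cebpz overlaps Cebpzos. Across the 2117 marked genes of at least 10 kb, 75.1% had more coverage in replicate 1, with a median difference of 4.69 percentage points. Replicate 1 also had the larger covered length, and with 2 replicates of 1 group no test of such differences was possible.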

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

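Peaks on contigs outside chromosomes 1 to 19, X and Y entered no comparison. There were 21 in replicate 1, 23 in replicate 2, 29 in the pooled list and 9 in the replicated list. No explanation was tested for them.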

How the results depend on the processing

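The ratio of X to autosomes in single replicates was chosen as an alternative after the data were seen, and all others before. Every setting kept most peak bases in gene bodies, the late position in genes, the exon excess and the deficit on X. The overlap of replicates, 32.8% of the union, was 29.6% with a −log10 q of at least 2, 16.2% with at least 5, 32.8% with equal numbers of peaks, 27.4% with the 50000 highest peaks of each, and 47.1% after joining peaks within 1 kb. Shared peaks averaged 45.7% when 50% of the peak had to be shared. Replicated peaks found in both replicates were 81.0% with 1 base and 3.05% with 90% of the peak. The ratio of X to autosomes was 0.0373 in the replicated list and 0.0494 to 0.0623 in single replicates. Domains numbered 19842 with a gap of 3 kb and 53702 to 56971 in single replicates. The share in gene bodies was 94.7% in the pooled list and 94.4% to 94.9% in single replicates. The ratio of late to early bins was 3.84 over all protein-coding genes of at least 10 kb and 3.36 to 3.73 in single replicates, with genes called marked in that replicate alone. The exon ratio was 1.49 with first exons and introns kept and 1.34 to 1.42 in single replicates, with genes called in the same way. Marked genes numbered 5136 at 10%, 697 at 40% and 3216 to 3795 in single replicates. The cause of these shifts was not tested, apart from what stricter limits remove by construction.

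With a −log10 q of at least 5, shared peaks averaged 30.6%, the ratio of X to autosomes was 0.0154, the share in gene bodies 96.0%, the late to early ratio 5.17, the exon ratio 1.49 and the number of marked genes 157. Under this setting 9 of the lists called below lost that call: squamous forestomach (percentile 2.85), gastric mesenchyme transcription factors (4.44), intestinal epithelium (3.42), pancreas (1.48), skeletal and cardiac muscle (1.30), anterior Hox (1.39), posterior Hox (10.04), histone (6.01) and keratin-associated protein genes (12.1). Posterior Hox and keratin-associated protein genes stayed at 0% coverage, so by construction only ties with random lists raised their percentiles, and for the other lists the cause was not tested. Without overlapping genes the call ended for mature gastric gland products (1.72), gastric mesenchyme transcription factors (2.01), anterior Hox (4.06), posterior Hox (1.04), histones (3.97) and keratin-associated protein genes (1.01). Mature gastric gland products stood at 1.32 in the replicated list, and histones at 0.0050 to 2.15 in single replicates. Of 186 list percentiles under alternatives, 169 kept their call, and none changed side. Of 552 coverages of named genes, 449 stayed within 1 SD and 103 moved, all under the stricter q or in the replicated list. A single replicate lies within 1 SD of the mean of 2 by construction, so those values could not move. Read depth is unknown, so weak genes below the peak limit stay undetected.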

Other observations

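The tests on the X copies, on broadly used X genes, on reads of X and of the joint matching of exon windows were chosen after the results were seen; the other tests below were fixed before their results.

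Long genes and non-coding genes added to the picture, and those named here were chosen after their values were seen. Of the genes of 100 kb or more, 32 were marked. Ubr4 led with 62.2% ± 2.83 (SD, n = 2), followed by the chromatin remodeller gene Chd2 (46.1% ± 9.25), the growth kinase gene Mtor (37.4% ± 1.60) and Ep400 (36.4% ± 3.48). Of 8201 long non-coding genes of at least 2 kb, 216 were marked, but among the 4098 that lay over 5 kb from any protein-coding gene only 5 were. These were Snhg17 (47.6% ± 4.22), Mir17hg, the host of a microRNA cluster (29.6% ± 1.84), 2700038G22Rik (24.7% ± 0.127), Mirg (23.4% ± 2.86) and Lncppara (21.4% ± 0.786). Of the 36436 domains, 87 lay over 5 kb from every annotated gene, the longest being 5.89 kb on chromosome 2 (84587593 to 84593483), with 41.9% ± 10.5 of its bases in peaks.

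The mark ran past gene ends. In 335 marked genes of at least 10 kb with no other protein-coding gene within 10 kb on either side, 27.9% ± 2.72 of the first kb after the end was in peaks, and 10.6% ± 1.06 of the 5 kb after it. The last kb before the start held no peak, and the 5 kb before it 0.340% ± 0.0228. On X, the highest peak by the authors' fold (5.39) lay within Mid1 (169988524 to 169989477), followed by peaks in Eif2s3x (4.31) and Kdm5c (4.14).

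The first pattern weighed was the lack of peaks on X. Autosomal genes matched to X genes on length and GC content had 7.36 times their mean coverage, and at least 6.14 times in each of 1000 draws, which argues against both as the whole cause. The 7 X members of the housekeeping, cell cycle, H3K36 and ribosomal lists had 0.0948 of the mean coverage of their 148 autosomal partners. For these 7 genes a lack of broadly used genes is not enough. They were not matched to their partners on length, and they are few among the broadly used genes of X. Fewer reads on X, which males carry once, were weighed next. Autosomal coverage in the sparser replicate was 0.619 of that in the pooled list, although its share of the reads is unknown. That comparison changes the whole library and its peak calling together, not X against the autosomes of 1 library. It therefore cannot decide whether fewer reads on X cause the lack of peaks. A candidate explanation is that 1 copy of X is used in each cell while the control counts all copies. The 9 genes known to be used from both copies averaged 8.28% against 2.67% for 7 other broad X genes (two-sided exact permutation p = 0.131). With the first set of 10 genes the two-sided exact permutation p was 0.177, but that set wrongly held Xist, used from the silent copy alone. The sets were not matched on length, and the 7 include the ribosomal protein genes Rpl39, Rpl10, Rps4x and Rpl36a. Some X genes outside both sets, picked after their values were seen, were covered like the highest of the 9. Flna had 29.5%, Maged1 24.3% and Hcfc1 21.1%, against 24.7% at Kdm5c and 19.9% at Eif2s3x, while X genes of at least 2 kb averaged 0.937%. The comparison leaves the explanation open with the sexes pooled. An effect of peak calling on X was not tested since the signal tracks were not examined.

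The second pattern was the exon excess. Between 100 bp windows of the same gene and a matched position in it the ratio was 1.21, between windows of the same gene and GC class 1.16, and between windows of the same gene without repeats 1.18, and none met the bounds set for or against an explanation in both replicates. With all of these matched together it was 1.04 ± 0.00177 (SD, n = 2), but only 42.5% of exon windows and 16.5% of intron windows could be so matched, and in those windows the ratio within genes was 1.06 before matching, a check added after the 1.04 was seen. Position, GC content and repeats may therefore account for part of the excess and cannot be told apart here from an effect of exons themselves. No biological explanation was tested.

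The third pattern was the place of the strongest peaks. Of the 883 replicated peaks in the highest 1% by fold, ties included, 106 lay at Zfp-named genes, against 1826 of all 83173 replicated peaks, and 73 such genes had at least 1. Of the 32-base words in those peaks, 96.9% occur once in the genome, as do 97.6% of the words in the other strongest peaks. Exact copies elsewhere were thus rare, but near copies that differ by a base were not counted. The alignments had also been filtered before peaks were called, by a rule not stated here. The share therefore cannot decide whether reads shared between related genes raised those peaks. Lying in an exon of 1 kb or longer does not alone account for it. Among peaks mostly within such exons, 13.1% (95% exact interval 10.3 to 16.4) were among the strongest at Zfp-named genes. At other genes it was 1.46% (1.19 to 1.77), a ratio of 8.99. The intervals count peaks as independent, although a gene can hold several. Exon length above 1 kb was not matched, so an effect of still longer exons stays open. Other technical explanations, and any biological one, were not tested.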
